A study of Mus musculus with 6 samples.

How the data were processed

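Total RNA of the hippocampus of each of 6 mice, 3 wild type and 3 Nrf2 knockout, was digested with RNase R, amplified by random priming, labelled with Cy3 and hybridised to 1 Arraystar mouse circRNA array, with 1 µg of labelled cRNA, per the labels' protocols. The arrays have 1 colour. Each scanner file is the output of Agilent Feature Extraction 11.0.1.1 with the protocol GE1_1100_Jul11, per the file headers. It holds an intensity per spot that the software had already corrected for background and spatial trend, with no scaling between arrays, per the file headers. The deposited series table holds the authors' processed values on a log2 scale for 13817 of the 14236 circRNA probes. Set against the scanner values of the same array, it correlated at 0.997 to 0.9998 with the raw median spot intensity and at 0.979 to 0.990 with the processed signal, and the medians of its columns were 7.22, 7.23, 7.22, 7.23, 7.25 and 7.25. The values are thus on a log2 scale and not centred per probe. Its filter and its exact normalization are not given in the sources used here; the submitters' processing notes name Feature Extraction and limma without their steps.

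Each array had 15712 spots, of which 15176 were not control spots. Spots flagged as non-uniform outliers were left out, no spot was saturated, and the spots of a probe were averaged on the log2 scale. The log2 processed signal was scaled by subtracting the array's 75th percentile over the circRNA probes. A circRNA was tested where its probe was well above background on at least 3 of the 6 arrays (a probe with 10 spots counted where at least 50% of its spots were), which kept 13409 circRNAs, and 13398 had enough measured arrays for a test. Of the 94 replicated probes, the mRNA and control circRNA probes well above background on an array were used for the spread between spots. Their median SD was 0.061 to 0.093 on the log2 scale, depending on the array. Tests were made with lmFit and eBayes in limma 3.58.1 (R 4.3.3, the data.table package in version 1.17.8, statmod 1.5.0) with genotype as the single term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Single values per array were compared with an exact permutation test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

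The scan was taken from the file headers. Scan 1 held 4 arrays (wild type 1 to 3 and knockout 1) and scan 2 held 2 arrays (knockouts 2 and 3), which occupied slide positions already used in scan 1 and so lay on another slide. Scan and slide are therefore the same split here. The scan was fitted as a block and the comparison repeated within scan 1. Both estimates rest on knockout 1 alone, and a circRNA with no usable spot on knockout 1 has no such estimate.

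The 50 mRNA probes carry transcript accessions, and 44 of them matched a gene symbol in a RefSeq table of the assembly GRCm38.p6. After the filter 44 mRNA probes were tested, 38 of them with a symbol. They were fitted together with the circRNAs and adjusted over the list alone and over all 13453 probes, and camera in limma tested them as a set against the circRNAs and fry as a set on its own. This comparison was not planned before the data were examined.

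The rule for named items, fixed before the data were examined, covered up to 24 circRNAs with the largest changes, and other items. Those circRNAs were to be calls whose arrays did not overlap between genotypes, each named with its host gene. Only the 2 such probes that rose most and the 2 that fell most, among those measured on all arrays, are named here. The files do not pair circRNA probes with host genes, classes or sequences. For that reason the gene lists, marker lists, classes and host gene comparisons fixed beforehand were not run. The mRNA probes named in the text are 17 of the 18 with a symbol that passed, together with others chosen after their values were seen, and 1 gene is not reported here.

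The alternatives were other normalizations (quantile, the median, the 75th percentile over other probes), normexp background correction with an offset of 50, the authors' processed values, other filters on dim probes, other variance models, the replicate number or the scan as a block, outlier spots kept, each array left out in turn and other thresholds. The files used here hold no mean spot signal, so that normexp was run on the median spot and background signals in its place. Simulated data held 13336 circRNAs on the real arrays' scale, of which 200 were changed, in 20 runs. Their noise was independent between circRNAs and held no scan effect, so the rates need not hold for the real arrays. The fit was tested on these data. Without the scan block it recovered 44.2% of 2-fold and 97.0% of 4-fold changes with 8.3 false calls per run, and with the scan block 2.2% and 73.8% with 5.5 false calls.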

Results

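Hippocampal RNA of 6 male mice of the ICR strain, aged 3 to 4 months, was profiled on 1 circular RNA array per mouse. Of these, 3 mice were wild type and 3 lacked Nrf2, the transcription factor encoded by Nfe2l2 that switches on antioxidant and detoxification genes. The RNA had been treated with RNase R, an exonuclease that degrades linear RNA and spares closed circles, so that circular RNAs (circRNAs, back-spliced transcripts without free ends) were enriched before labelling. Each array held 14236 circRNA probes with 1 spot each and 50 probes for mRNAs with 10 spots each. The 75th percentile of the circRNA signal was 402, 374 and 231 intensity units on wild-type arrays 1 to 3 and 382, 481 and 331 on knockout arrays 1 to 3. The number of arrays, 3 per genotype, limits the precision of every comparison. The targeted gene was not analysed here, because the files do not pair a probe with Nfe2l2, so the genotype labels were not checked against its level.

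The number of circRNAs detected did not differ between genotypes beyond the spread between mice. Wild-type hippocampi had 13285 ± 171 circRNA probes well above background (SD, n = 3) and knockout hippocampi 13276.7 ± 433 (SD, n = 3), a difference of -8.33 that was smaller than either spread (exact two-sided permutation test, p = 1, with 0.1 the smallest p that 3 against 3 allows). The sign of this difference was not stable, and it was 17.2 without wild type 1, 61.7 without wild type 2 and 238.5 without knockout 1. On all 6 arrays 12587 circRNA probes were well above background, and 418 were so on none. Knockout 1, scanned together with the wild-type arrays, had 12783 such probes, below the lowest wild-type array at 13094, and knockouts 2 and 3 of the other scan had 13590 and 13457, above the highest at 13425.

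Along the first principal component of the circRNA profiles, which carried 62.1% of the variance, the scan 2 knockout arrays lay apart from the wild-type arrays, with knockout 1 in between. The wild-type arrays lay at -47.6, -19.2 and -40.1, knockout 1 at 4.14, and knockouts 2 and 3 at 45.3 and 57.5. The headers placed the 6 arrays in 2 scans: the 3 wild-type arrays and knockout 1 shared scan 1, and knockouts 2 and 3 shared scan 2. Correlations across circRNAs, which are not independent replicates, were 0.979 among wild-type arrays, 0.958 to 0.976 among knockout arrays and 0.910 to 0.983 between genotypes. The highest of all pairs, 0.983, was that of knockout 1 with wild type 2. The median SD of a circRNA between arrays was 0.191 on the log2 scale in wild type and 0.275 in knockout. The knockout arrays span both scans and the wild-type arrays only scan 1, so this SD cannot part mice from scans. Among knockout arrays the pair of scan 2 correlated at 0.976, and the pairs across scans at 0.968 and 0.958.

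**Figure D1:**
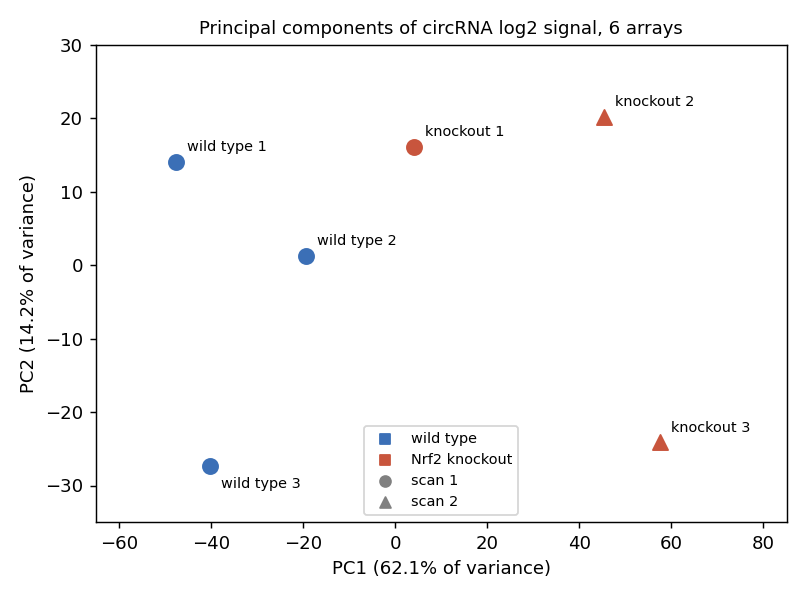
Principal component 1 (horizontal axis, 62.1% of the variance) and 2 (vertical axis, 14.2%) of log2 circRNA signal, with 1 point per array, coloured by genotype and shaped by scan. Knockout 1 of scan 1 lies at 4.14 on the horizontal axis, between the wild-type arrays (all below 0) and knockouts 2 and 3 of scan 2 (45.3 and 57.5).

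The study's stated purpose was to compare hippocampal circRNA profiles with and without Nrf2. Of 13398 circRNAs tested, 22 passed an adjusted p of 0.05 in limma, of which 16 were lower and 6 were higher in the knockout. Each differed by at least 2.23-fold. Among the 20 of them measured on all 6 arrays, the largest fall was that of ASCRP4003110, whose log2 signal relative to the array's 75th percentile was -1.48 ± 0.40 in wild type and -4.35 ± 0.39 in knockout (SD, n = 3 each), 7.31-fold lower. ASCRP4003328 was 5.45-fold lower, while ASCRP4010314 was 4.08-fold higher and ASCRP4011695 3.47-fold higher in the knockout. The files name circRNAs by probe only, so their host genes are not given here.

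For these 4 circRNAs the log2 fold change of knockout against wild type was -2.87 (SE 0.273) for ASCRP4003110, -2.45 (SE 0.270) for ASCRP4003328, 2.03 (SE 0.244) for ASCRP4010314 and 1.80 (SE 0.215) for ASCRP4011695, each with a limma adjusted p of 0.0452. All 3 knockout arrays lay on one side of all 3 wild-type arrays for each of them, which was a condition for naming them and so is no further support. With the scan as a block, where the genotype effect rests on knockout 1 against the 3 wild-type arrays, the changes were -2.61 for ASCRP4003110 (adjusted p = 0.322) and -2.17 for ASCRP4003328, 1.71 for ASCRP4010314 and 1.72 for ASCRP4011695 (adjusted p = 0.382 each), and the changes within scan 1 were equal to these. After normexp with the 75th percentile the log2 changes were smaller, -1.47 for ASCRP4003110, -1.38 for ASCRP4003328, 1.25 for ASCRP4010314 and 1.31 for ASCRP4011695, and all 4 passed. After normexp with quantile normalization they were -1.36, -1.28, 1.33 and 1.36 in the same order and none passed (limma adjusted p = 0.0740 each). In the authors' processed values they were -1.92, -1.71, 1.71 and 1.62, and none passed. Among the 22, 1 other circRNA was not well above background on any knockout array, and 2 had spots free of outlier flags on only 3 and 4 arrays. Both were called lower. That with 3 arrays had its knockout value from knockout 3 alone, and that with 4 arrays from knockouts 2 and 3 of scan 2.

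**Figure D2:**
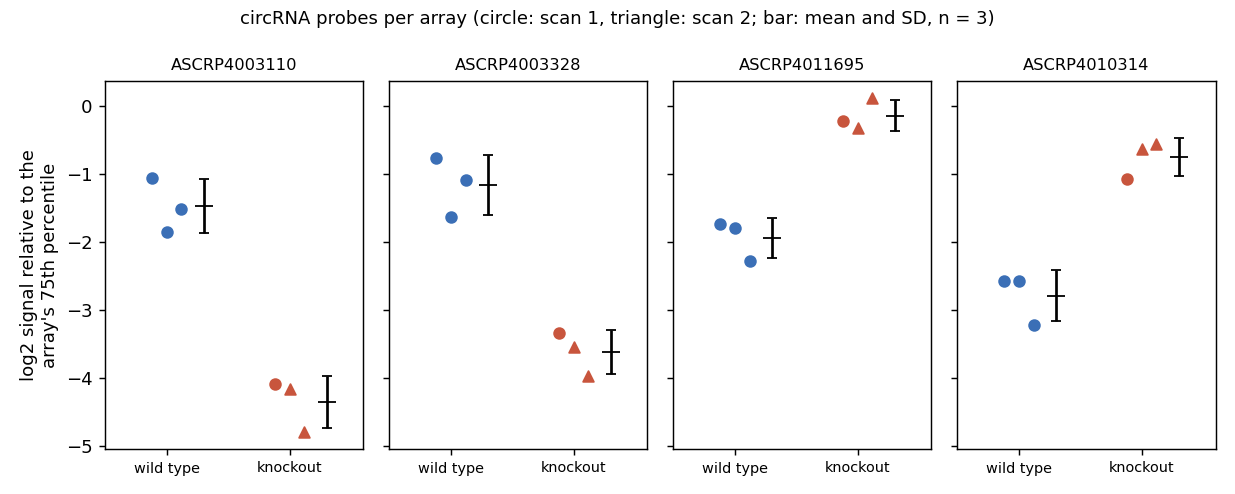
Log2 signal relative to the array's 75th percentile (vertical axis) of 4 circRNA probes in wild-type (blue) and Nrf2 knockout (red) hippocampi, with 1 point per array, circles for scan 1 and triangles for scan 2, and bars for the mean and SD (n = 3). ASCRP4003110 and ASCRP4003328 were lower and ASCRP4011695 and ASCRP4010314 higher on every knockout array, knockout 1 of scan 1 included. The 4 probes were picked among calls whose arrays did not overlap between genotypes.

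Beyond the calls, a looser rule was counted as a description. An unadjusted p under 0.05 was reached by 3656 circRNAs against 669.9 expected by chance, and 2611 of them differed by at least 1.5-fold, 1606 lower and 1005 higher in the knockout. Log2 fold changes below -1 were found for 6.14% of circRNAs and above 1 for 1.30%. With circRNAs parted by mean signal into 4 groups of equal size, 557 were lower and 253 higher by this looser rule in the brightest group and 419 were lower and 210 higher in the dimmest, while the middle groups were closer to balance (303 lower and 262 higher, and 327 lower and 280 higher). For 4479 circRNAs, 33.6% of those measured on all arrays, the genotypes did not overlap, where chance gives 10%, and of these 2296 were lower and 2183 higher.

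The count of 22 depended on the scan and on single arrays. With the scan as a block, limma called 0 circRNAs at an adjusted p of 0.05, with 1188 at an unadjusted p under 0.05 and 1032 by the looser rule, and within scan 1 alone it called 0, with 1222 and 1029. The scan term of the blocked fit had 1 call, with 1786 at an unadjusted p under 0.05 and 1652 by the looser rule, and scan 2 against scan 1 with the genotype left out gave 1082 calls and 3039 by the looser rule, both above the genotype's 22 and 2611. The block could be estimated for 20 of the 22, and all 20 kept their direction with an unadjusted p under 0.05, although they had been chosen on data that include knockout 1. The count was 1995 without knockout 1, 377 without wild type 2, 5 without wild type 3 (4 higher and 1 lower), and 0 without wild type 1, knockout 2 or knockout 3. Without knockout 1 the genotypes and the scans are the same split, so the 1995 cannot tell genotype from scan. The number of calls was also 0 in the authors' processed values, with 3850 at an unadjusted p under 0.05, and 4 after quantile normalization. After normexp background correction it was 423 with the 75th percentile and 0 with quantile normalization, the latter with 3686 at an unadjusted p under 0.05.

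The array's mRNA probes can read linear transcripts left after RNase R or circles that hold the probed exon, which were not separated here, and their comparison was added after the data had been seen. Of 44 such probes tested, 39 were lower and 5 higher in the knockout at any p. Adjusted over the list alone, 19 passed as lower and 0 as higher. Those 19 included the probes for Gpi1, an enzyme of glycolysis, 3.45-fold lower, Duox1, an oxidase that makes hydrogen peroxide, 2.98-fold lower, and Ppara, a nuclear receptor for fatty acids, 2.54-fold lower. By contrast, Actb, the cytoskeletal actin gene, and Apoe, the main lipid carrier of the brain, had log2 fold changes of 0.04 (SE 0.198) and 0.10 (SE 0.192) and did not pass.

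Log2 signal of Gpi1 was 2.09 ± 0.48 in wild type and 0.31 ± 0.62 in knockout (SD, n = 3 each), a log2 fold change of -1.79 (SE 0.358, limma adjusted p = 0.0156 over the list alone). That of Ppara went from -2.29 ± 0.20 to -3.63 ± 0.62 (log2 fold change -1.34, SE 0.309, adjusted p = 0.0198). Duox1 fell by 1.58 on the log2 scale (SE 0.394, adjusted p = 0.0238). Also among the 19 were Acaa2, a thiolase of mitochondrial fatty acid oxidation (-1.02, SE 0.219), Pex11a, a peroxisomal membrane protein (-0.58, SE 0.161), and Gamt, an enzyme of creatine synthesis (-0.63, SE 0.175). Cpt1a, the gate of fatty acid entry into mitochondria, had a log2 fold change of -0.37 (SE 0.223) and did not pass (adjusted p = 0.211).

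Further probes that passed belong to genes of varied function. E2f1, a driver of the cell cycle, fell by 0.98 on the log2 scale (SE 0.204) and Lhx1, a LIM homeodomain factor, by 0.51 (SE 0.165). After normexp background correction E2f1 passed with neither scaling, while Lhx1 did not pass with the 75th percentile (limma adjusted p = 0.0725) and passed with quantile normalization (-0.40, limma adjusted p = 0.0270). Gabrg1, a subunit of the GABA type A receptor, fell by 1.89 (SE 0.655, adjusted p = 0.0488) and Tm9sf1 by 1.33 (SE 0.395). The probe for Dnajc11, a mitochondrial J-domain protein, also passed (adjusted p = 0.00927), but its change was smaller after normexp. Falls between 0.60 and 0.93 were measured for Cep41, Il2, Anxa8, Olfr166, Lhfp and Spats1, and of the rest of the 19 probes 1 matched no gene symbol. Several of these probes were dim: Dnajc11 and Cep41 were well above background on 2 of 3 wild-type and 1 of 3 knockout arrays, and E2f1, Acaa2, Il2 and Gabrg1 on all wild-type and 2 of 3 knockout arrays. All 6 changes were smaller after normexp, which started from median spot signals and so changed more than the background correction.

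The other 25 probes did not pass. Among them Gsta4, a glutathione transferase that detoxifies lipid aldehydes, had a log2 fold change of -0.05 (SE 0.303). Prdx2, a peroxiredoxin, had -0.36 (SE 0.162, adjusted p = 0.105), with all 3 knockout arrays below all 3 wild-type arrays. Mbp, the myelin basic protein gene, had -0.36 (SE 0.359), and Chgb, a secretory granule protein of neurons, had -0.62 (SE 0.284, adjusted p = 0.105).

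**Figure D3:**
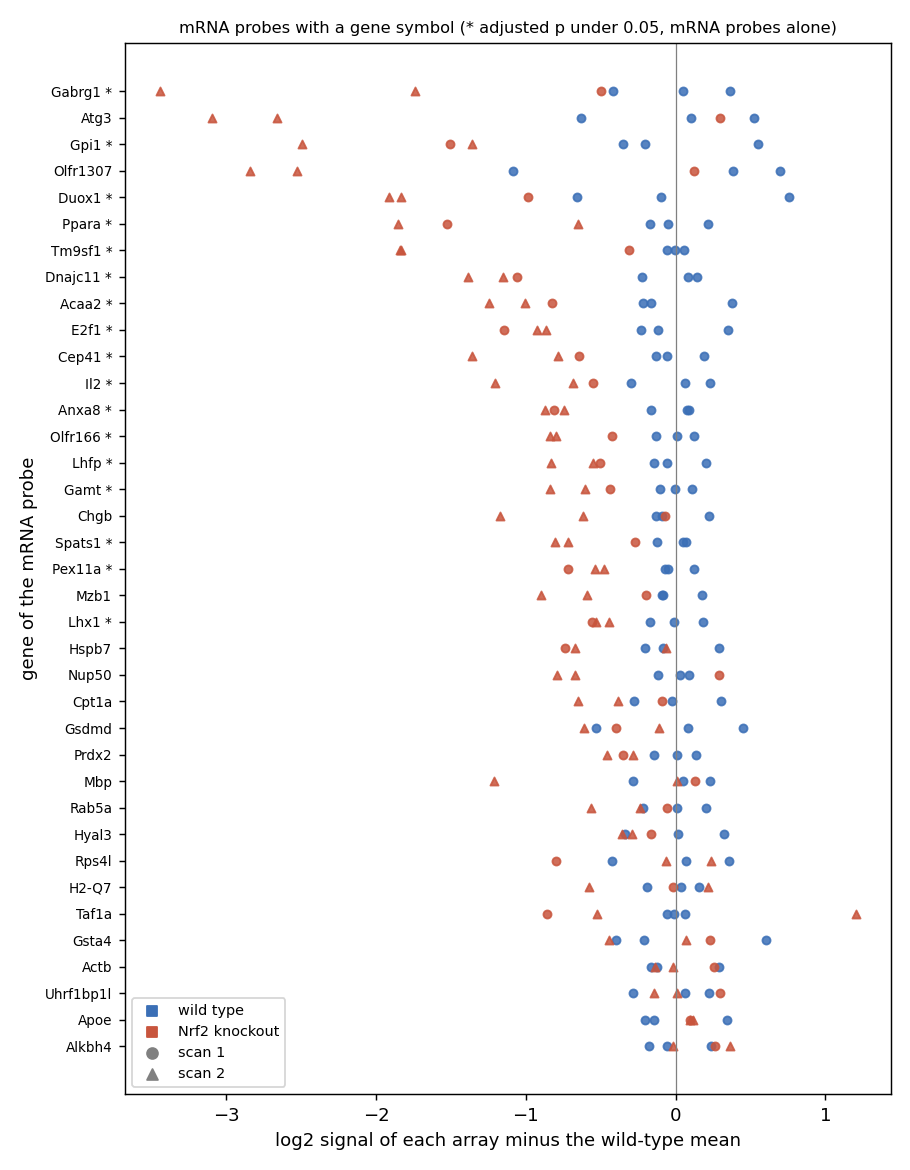
Log2 signal of each array minus the wild-type mean (horizontal axis) for 37 of the 38 tested mRNA probes with a gene symbol (vertical axis), with 1 point per array, blue for wild type, red for knockout, circles for scan 1 and triangles for scan 2. The 17 probes marked with an asterisk passed the list-alone threshold and were all lower in the knockout, and Apoe and Actb lie near 0.

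As a set, the mRNA probes were lower than the circRNAs in the knockout, with a median log2 fold change of -0.59 (camera in limma with a preset correlation of 0.01, p = 1.48e-09, and p = 0.0449 with an estimated correlation, while fry, which tests the set on its own, gave p = 0.0053). The estimated correlation between the mRNA probes was 0.124, above the preset of 0.01. With the scan as a block the set's median was -0.31, and the median within scan 1 was the same value. Both of these medians rest on knockout 1 alone against the 3 wild-type arrays. They therefore cannot show whether the fall holds across knockout mice once the scan is allowed for. The median over the mRNA probes was -3.09, -2.99 and -2.91 on the wild-type arrays, -3.38 on knockout 1 and -3.90 and -3.31 on knockouts 2 and 3 (exact two-sided permutation test, p = 0.1, the smallest possible). Single probes passed only within their own list: adjusted over all 13453 probes 0 passed (lowest limma adjusted p = 0.0711, with 21 at an unadjusted p under 0.05), and with the scan as a block 0 passed over the list alone (lowest adjusted p = 0.118, with 8 at an unadjusted p under 0.05). Of all 44 probes 35 were lower on knockout 1 than the wild-type mean; the 19 were all among them, but they had been chosen on data that include knockout 1. On knockout 1 the log2 difference was -1.51 for Gpi1, -1.53 for Ppara and -0.98 for Duox1, but only -0.31 for Tm9sf1, -0.27 for Spats1 and -0.50 for Gabrg1, whose lower signal was mostly in the scan 2 knockouts. The count was 7 without wild type 1, 6 without wild type 2 or wild type 3, 25 without knockout 1, 1 without knockout 2 and 9 without knockout 3. Without knockout 1 all knockout arrays are of scan 2, so the 25 cannot tell genotype from scan. After normexp with the 75th percentile the set's median was -0.35, and 8 of the 18 genes with a symbol still passed. Among them were Gpi1 (-1.66), Duox1 (-1.15), Ppara (-0.70), Tm9sf1 (-0.74), Olfr166 (-0.60), Gamt (-0.51) and Pex11a (-0.49). In contrast, Dnajc11 was at -0.34, Gabrg1 at -0.45, E2f1 at -0.39, Acaa2 and Cep41 at -0.35 and Il2 at -0.32, none of which passed. After normexp with quantile normalization the set's median was -0.15 and Tm9sf1 no longer passed (limma adjusted p = 0.0522). Lhx1 and Anxa8 did pass (limma adjusted p = 0.0270 each), which they had not with the 75th percentile. The dim probes were then at -0.10 for Dnajc11, -0.21 for Gabrg1, -0.18 for E2f1, -0.13 for Acaa2, -0.11 for Cep41 and -0.09 for Il2.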

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

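The tests of explanations in this part were all chosen after the results they bear on had been seen. Of the 15 probes that the array names as negatives, 4 were well above background on all 6 arrays, a signal in data that no comparison uses. Their mean log2 signal was between -4.46 and -3.37 relative to the array's 75th percentile, and that of the other 11 was between -7.67 and -7.30. Of the circRNA probes 22.8% had a mean signal below that of the brightest of these 4. The median of the other 11 differed between arrays. It was -7.51, -7.49 and -6.99 on wild type 1 to 3, -7.06 on knockout 1, and -8.45 and -8.00 on knockouts 2 and 3. This floor was thus lowest on the scan 2 knockouts, and whether it contributed to lower values of dim probes there was not tested.

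The knockout arrays were shifted from the wild-type arrays over many circRNAs, and the scan and the genotype overlap. Of the 10 splits of the 6 arrays into 3 and 3, only 1, the real one, gave as many calls (22 against at most 0 in the others) or as many circRNAs by the looser rule (2611 against at most 817), and with 10 splits the share cannot fall below 0.1; the scan grouping, 4 against 2 arrays and so not among these splits, gave 1082 calls and 3039 by the looser rule. The circRNAs were ranked without the arrays being compared, first from 1 scan 2 knockout and 2 wild-type arrays. There knockout 1 was shifted from the held-out wild-type array toward the scan 2 knockouts by 0.295 to 0.507 (log2, over 6 rankings). In rankings from only 1 wild-type array, knockout 1 lay 0.391 to 0.893 from the other wild-type arrays, which lay 0.024 to 0.408 apart. Ranked from knockout 3 and wild type 3, knockout 1 lay 0.392 from wild type 2, less than the 0.408 between wild-type arrays. These ranges overlap and rest on 1 knockout array, so the second scan as the whole cause was not excluded. In the first rankings the shift of knockout 1 was 0.308 to 0.456 of that of the other scan 2 knockout. This lies below the ratio of 1 that the genotype as the whole cause would give, but it rests on 1 array. A genotype effect, a scan effect and their sum cannot be told apart, since scan 1 holds a single knockout mouse.

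Of the 44 mRNA probes, 39 were lower in the knockout at any p, and 19 passed over the list alone, all of them lower. Only 1 of the 10 splits, the real one, gave as many that passed (at most 1 in the others). Again there were too few splits for a share under 0.05. The brighter probes had a median log2 fold change of -0.62 (95% bootstrap interval -0.81 to -0.43), and of -0.49 after normexp. With this scaling, background subtraction acting on dim probes does not account for the lower median of the brighter probes on these 6 arrays. After normexp with quantile normalization the whole set was at -0.15, and the brighter probes were not looked at alone. Background subtraction stays open for the dimmer probes, whose median was -0.28 after normexp, an offset that shrinks dim changes by construction. The bootstrap intervals in this paragraph cover the spread between probes of the same arrays, not between mice. Less linear RNA left after RNase R in the knockout samples may contribute. A set of 6 mRNAs taken as abundant (Apoe, Actb, Mbp, Chgb, Prdx2 and Gamt) had a median of -0.36 (95% bootstrap interval -0.62 to 0.07). The other mRNA probes had a median of -0.61 (95% bootstrap interval -0.90 to -0.39). The 6 were chosen after their values were seen, and they were not the brightest probes. Gpi1, at 2.09 in wild type, was brighter than all of them but Apoe (2.31) and had a log2 fold change of -1.79. The comparison therefore cannot decide, and this explanation stays open. The second scan alone also stays open: knockout 1 lay 0.288 below the lowest wild-type array in its median over the mRNA probes, more than the wild-type range of 0.179, but this is 1 array. Lower abundance of these transcripts in the knockout hippocampus remains an open biological explanation.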

How the results depend on the processing

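The mRNA comparison, the analyses within scan 1 and those with the scan as a random block were chosen after seeing the data. The 4 named circRNAs kept their direction in all 24 settings, with log2 fold changes of -3.06 to -1.36 for ASCRP4003110, -2.68 to -1.28 for ASCRP4003328, 1.25 to 2.19 for ASCRP4010314 and 1.31 to 1.90 for ASCRP4011695, and stayed past the threshold in 45 comparisons and lost it in 47. The mRNA probes with a symbol that passed also kept their direction, staying past it in 251 comparisons and losing it in 137. The 4 circRNAs were chosen as calls whose arrays did not overlap between genotypes, and the arrays of these mRNA probes did not overlap either. Leaving out an array, the scan block, the analysis within scan 1 or another filter or variance model could therefore not reverse a direction. The kept direction in these settings is no further support. Only settings that change the array values, such as another normalization, could have reversed it. The 22 calls lie close to the threshold (lowest adjusted p = 0.0452), and 1806 circRNAs had an adjusted p under 0.1, while a test against a fold of 1.2 (treat) left 0.

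Of 22 called circRNAs (6 higher, 16 lower), quantile normalization left 4 (1 higher, 3 lower), normexp with the 75th percentile gave 423 (89 higher, 334 lower, 14 shared), an intensity trend 14 (9 lower), a filter on probes well above background on all arrays 9 lower, and array quality weights 1231 (375 higher, 856 lower). The count was 0, with 0 higher and 0 lower, with normexp and quantile normalization (3686 at an unadjusted p under 0.05), the authors' values (3850), no filter on dim probes (3707), outlier spots kept (3685), the scan as a block (1188), within scan 1 (1222) and the scan as a random block (2862). Leaving out 1 array gave 0 to 1995 calls (0 to 714 higher, 0 to 1281 lower), highest without knockout 1. Without knockout 1 every knockout array is of scan 2 and every wild-type array of scan 1. No count from that setting can tell genotype from scan. The looser count of 2611 was 1418 with normexp and the 75th percentile, 1419 with normexp and quantile normalization, 1032 with the scan as a block, 1029 within scan 1 and 950 at a fold of at least 2. Its share higher in the knockout was 38.5%, and 47.6% after quantile normalization, 48.3% in the authors' values and 28.8% after normexp with the 75th percentile. The 19 mRNA probes lower in the knockout became 9 with normexp and either scaling, 9 with the scan as a random block, 0 with the scan as a block or within scan 1, 0 adjusted together with the circRNAs, and 1 to 25 with 1 array left out. The difference in detected probes of -8.33 was -105 by the software's test for a positive and significant signal and -165 to 238.5 with 1 array left out, and it reversed to 17.2 without wild type 1, 61.7 without wild type 2 and 238.5 without knockout 1. The scan block and the analysis within scan 1 rest on a single knockout mouse; the cause of the other changes was not tested.

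No label says that the replicate numbers pair the mice. Deviations of same-numbered arrays correlated at 0.19, -0.04 and 0.21, which cannot settle whether they do. With the replicate block there were 430 calls (47 higher, 383 lower) and 21 mRNA probes, and the estimated-correlation p of the mRNA set was 0.138. Not run were the alternatives for gene lists, marker lists, classes, circRNAs of the targeted gene and shared host genes, which need a host gene per probe. Signal over background limits the 418 circRNA probes that were not well above background on any array.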

Other observations

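The values in this part were looked at after the data had been seen. Some mRNA probes differed between the scan 2 knockouts and all scan 1 arrays, knockout 1 included. Atg3, an enzyme that attaches lipid to the autophagy protein LC3, had log2 signals of -2.83, -2.41 and -3.56 in wild type and -2.64 in knockout 1, and -5.59 and -6.02 in knockouts 2 and 3. Olfr1307, an olfactory receptor gene, had 2.24, 1.93 and 0.46 in wild type, 1.66 in knockout 1, and -0.99 and -1.30 in knockouts 2 and 3. Tm9sf1 had -2.41 in knockout 1, and -3.93 in knockouts 2 and 3 alike, against -2.10 ± 0.06 in wild type (SD, n = 3). The probes for Tyr, Bambi and Cav2 were not well above background on any array, and those for Kcnn2 and Trp53rka were so on 1 wild-type array each and on 0 knockout arrays. The probe for Carhsp1 went the other way, well above background on 0 wild-type and 2 knockout arrays (mean log2 signal -6.27 and -5.75).

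The array also carries 14 control circRNA probes with 10 spots each. Their log2 fold changes of knockout against wild type ran from -0.57 to 0.57, with 10 of 14 lower, and 0 passed adjusted over the list alone in limma (lowest adjusted p = 0.0699, with 4 at an unadjusted p under 0.05). Of 15 custom probes without a gene name, 11 were lower on both scan 2 knockouts than on all 4 scan 1 arrays, with a median difference from wild type of -0.84 in the scan 2 knockouts and -0.19 in knockout 1, and knockout 1 lay inside the wild-type range for 7.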
